A study of Mus musculus with 8 samples.

How the data were processed

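RNA was extracted with a column kit for small samples from granulosa cells of mice aged 1 day (PND1) or 4 days (PND4) after birth, with 4 libraries per age, and libraries were made by standard Illumina procedures, per the labels' protocols. Reads were trimmed with Trim Galore and aligned with HISAT2 to GRCm38, per the submitters' processing notes, which give no versions. The authors deposited 1 table of FPKM values for the 8 libraries, per the file headers. The program that made the FPKM values, the annotation it used and whether it used strand are not given in the sources used here. Its 11783 rows are a filtered set, per the file's name, and the filter is not given in the sources used here. The authors deposited a second table with a fold (a ratio of PND1 over PND4, a direction read from the values), its log2, a p-value and a q-value per gene. Its test is not given in the sources used here, and it was used only for counts beside those computed here. Its log2 ratio had a correlation of -0.951 across genes with the log2 PND4 minus PND1 difference of the FPKM, as the opposite coding requires.

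The values are FPKM and not read counts, so the planned count test was replaced by the test planned for such units. Values were taken as log2(FPKM + 1), and a fold on this scale understates the change of genes with low values. Genes with at least 1 FPKM in at least 4 libraries were kept, 10756 of 11783, which left 1027 untested. The ages were compared with limma 3.58.1 in R 4.3.3, with a mean-dependent prior variance and no block, as PND4 minus PND1, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Low values of 2467 genes with a single annotated transcript were searched for whole multiples of 1 read. Between 17.3% and 22.8% of them lay within 0.1 of a multiple, where 20% would by chance, so whole reads were not recovered and the depth stays unknown. The median 95% interval of a gene's log2 difference reached 0.65 to either side, and 0.45 in the upper part of expression.

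Lists of genes for pathways, cell types and technical signs were fixed before the data were examined, as were the grouping, the tests and the alternatives planned. Each of the 35 lists was tested with camera at a preset correlation of 0.01 and at an estimated correlation, adjusted over the lists. Summed FPKM of 10 marker lists was compared by exact permutation over 70 assignments of libraries to ages. The rule for genes to name took the largest changes among genes past the threshold whose libraries did not overlap between ages, with mean expression above the median of kept genes and a symbol other than a predicted locus or pseudogene. It took no gene. Foxl2, Kitl, Amh, Fst, Inhbb, Nr5a2, Lgr5, Cdkn1b, Zp3 and Gdf9 were named in any case, and for each list described up to 2 members with the highest mean expression where none passed. Other genes named, Gm16272 among them, and members past adjustment over a list alone were chosen after their values were seen. The values of 1 gene are not reported here.

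The limma and camera steps were tested on simulated data for the 10756 genes of this comparison, with 200 genes changed in each of 10 simulations. Of genes changed by 1.5-fold, 7.16% were recovered, of those changed by 2-fold 29.4%, and of those changed by 4-fold 68.2%. There were 743 calls, of which 41 were false. A list of 20 genes shifted by 0.4 on the log2 scale was called in 10 of 10 simulations, with genes simulated as independent, and 0 unchanged lists were called.

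Gene positions came from GENCODE M21 on GRCm38, in which 11770 of the 11783 gene identifiers were found. Alternatives covered scaling by median-of-ratios and upper-quartile factors, the filter on low values, the pseudocount (0.1 and 5), a minimum fold of 1.5, the replicate number as a block, and leaving out each library. Those chosen after seeing the data were robust variance estimation, array weights, leaving out both libraries numbered 1, rescaling without mitochondrial and ribosomal-RNA-like entries, permutation of list means, and for the lists also the upper-quartile, pseudocount and no-filter settings. Figures were drawn with matplotlib 3.10.9.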

Results

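Gene expression was measured by RNA-seq in 8 libraries of granulosa cells, the somatic cells that enclose the oocyte. The cells came from ovaries of C57BL/6 mice at postnatal day 1 (PND1, 4 libraries) or postnatal day 4 (PND4, 4 libraries). In this period primordial follicles form in the mouse ovary and the first of them begin to grow, and the series is framed around that activation. The deposited table lists 11783 genes as FPKM, a length-scaled and depth-scaled expression value, with totals over the listed genes between 443333 and 505035 per library. Read depth is unknown. Between 222 and 1234 genes per library were listed at exactly 0. Nothing in the labels says whether the 4 libraries of an age came from separate animals or litters, so p-values measure the spread between these libraries.

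The comparison asks which granulosa-cell transcripts differ between PND1 and PND4. One antisense gene, Gm16272 (ENSMUSG00000086582), passed the test, and it was lower at PND4. It had 29.2, 14.2, 22.6 and 12.8 FPKM in the 4 PND1 libraries and was listed at 0 in all 4 PND4 libraries (limma, adjusted p = 0.000654). Gm16272 lies on chromosome 6 from 39584092 to 39592784 on the minus strand (GRCm38) and has 2 exons. Exon 1, from 39592629 to 39592784, lies within exonic sequence of Ndufb2, a respiratory complex I subunit on the opposite strand, with 156 bases in common. Gm16272 also runs across Adck2 and Gm42420, without shared exonic bases. Ndufb2 itself had low values, from 2.25 to 5.42 FPKM over the 8 libraries, below those of Gm16272 at PND1. Its log2 difference was 0.12 (limma, unadjusted p = 0.720, adjusted p = 0.960). Whether the counting used strand is not given in the sources used here, so reads of Gm16272 and Ndufb2 cannot be assigned with certainty, and an exact 0 can be a failed estimate.

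Among the granulosa genes named in advance, none passed the adjusted test. On GRCm38 Foxl2 (ENSMUSG00000050397) lies on chromosome 9 from 98955288 to 98958543, and Kitl (ENSMUSG00000019966) on chromosome 10 from 100015630 to 100100416. Foxl2, the transcription factor that maintains ovarian somatic identity, stood at 15.9 ± 3.87 FPKM at PND1 and 17.5 ± 5.85 at PND4 (SD, n = 4). Its log2 difference was 0.12 (95% interval -0.43 to 0.68), and the sign turned without PND1 replicate 1 (-0.049) or without PND4 replicate 1 (-0.077). Kitl, which encodes the ligand of the oocyte receptor KIT, stood at 71.5 ± 13.2 and 67.7 ± 4.52 FPKM, with a log2 difference of -0.064 (95% interval -0.37 to 0.24), and that sign turned without PND1 replicate 2 (0.055). Follistatin (Fst) stood at 11.8 ± 3.72 and 9.22 ± 4.15 FPKM, the inhibin and activin subunit gene Inhbb at 12.5 ± 4.83 and 17.5 ± 4.03 FPKM, and the cell-cycle inhibitor gene Cdkn1b at 7.44 ± 4.17 and 10.7 ± 2.05 FPKM. Lgr5, a receptor of the ovarian surface and of a pregranulosa population, stood at 2.62 ± 1.70 and 1.20 ± 0.805 FPKM. The nuclear receptor gene Nr5a2 had the smallest p of the granulosa genes named in advance, with 2.19 ± 1.04 FPKM at PND1, 4.96 ± 1.89 at PND4 and a log2 difference of 0.90 (limma, unadjusted p = 0.0380, adjusted p = 0.805). Amh, a product of growing follicles, was listed at 0 in PND1 replicates 1 to 3 and at 0.239 FPKM in replicate 4. At PND4 it was listed at 0 in replicate 1 and at 7.87, 4.04 and 1.81 FPKM in replicates 2 to 4, and the filter on low values left it untested.

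The oocyte genes Zp3, for a zona pellucida protein, and Gdf9, for a secreted growth factor, were measured as signs of carried-over oocytes. Zp3 stood at 4.88 ± 5.53 FPKM at PND1 and 24.6 ± 24.5 at PND4 (log2 difference 2.32, limma unadjusted p = 0.00972, adjusted p = 0.740), with 61.3 FPKM in PND4 replicate 3. Gdf9 stood at 1.35 ± 1.27 and 6.23 ± 7.01 FPKM (log2 difference 1.27, unadjusted p = 0.0726, adjusted p = 0.805), with 16.4 FPKM in PND4 replicate 3 and a log2 difference of 0.69 without that library.

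**Figure D1:**
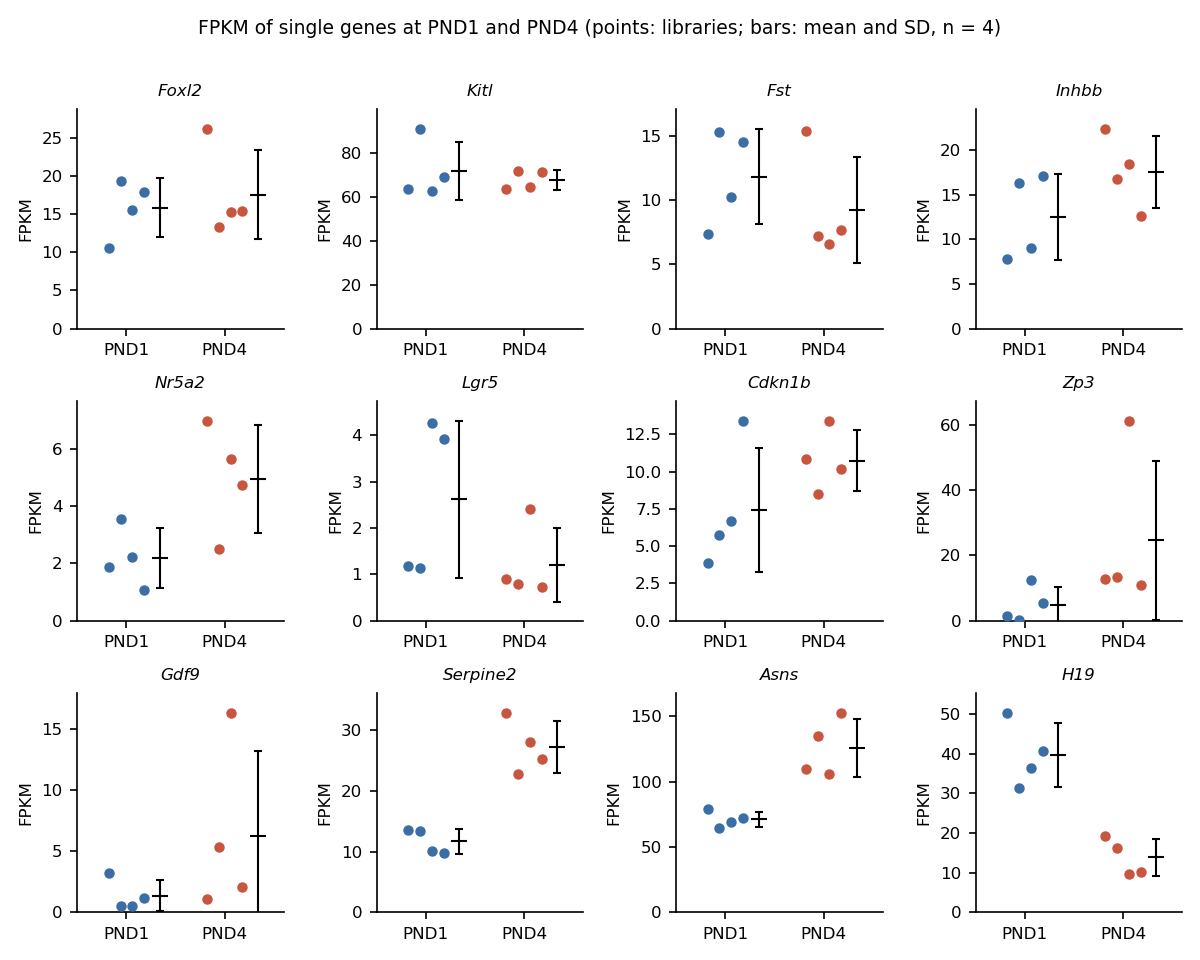
FPKM (vertical axis, linear, from 0) of 12 genes in each PND1 and PND4 library (points), with the mean and SD of 4 libraries (bars, ending at the axis where the SD exceeds the mean). Serpine2, Asns and H19 were chosen after their values were seen. Their PND1 and PND4 libraries do not overlap, while those of the other 9 genes do.

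Over all 10756 genes tested, 0 were called higher and 1 lower at PND4 (limma on log2(FPKM + 1), adjusted p under 0.05). An unadjusted p under 0.05 was had by 635 genes, where 538 would be expected on average with no difference. The spread around that average is wide, as other splits of the 8 libraries into 4 and 4 gave a median of 433 and up to 873. Of the 635, 437 were higher and 198 lower at PND4, but with median-of-ratios scaling 243 were higher and 323 lower. The smallest adjusted p after that of Gm16272 was 0.258. The rule set for naming the largest changes selected 0 genes, so the following genes were chosen after their values were seen. They come from the 15 genes with the smallest p in each direction, not in the order of p and with a preference for amino acid and stress genes, and none passed the adjusted test. Among genes with higher PND4 values, Serpine2 (ENSMUSG00000026249, chromosome 1 from 79794197 to 79861180), which encodes a serine protease inhibitor, stood at 11.7 ± 2.04 FPKM at PND1 and 27.2 ± 4.32 at PND4 (log2 difference 1.15, adjusted p = 0.258). Asns, for asparagine synthetase, stood at 71.1 ± 5.92 and 126 ± 22.1 FPKM. Mthfd2, for a mitochondrial folate enzyme, stood at 33.8 ± 6.01 and 60.6 ± 4.99 FPKM, and Phgdh, for the first enzyme of serine synthesis, at 93.5 ± 9.87 and 143 ± 17.0 FPKM. The stress-response transcription factor gene Atf4 stood at 85.1 ± 18.04 and 149 ± 25.7 FPKM, Serpinf1 at 29.9 ± 5.99 and 58.7 ± 9.28 FPKM, and the steroid-metabolising enzyme gene Akr1c14 at 13.5 ± 3.24 and 29.4 ± 5.04 FPKM. Among genes with lower PND4 values, the imprinted noncoding RNA H19 (ENSMUSG00000000031, chromosome 7 from 142575529 to 142578143) stood at 39.7 ± 8.04 and 13.8 ± 4.69 FPKM (log2 difference -1.49, adjusted p = 0.258). The vasopressin receptor gene Avpr1a stood at 9.45 ± 3.71 and 2.28 ± 0.778 FPKM, clusterin (Clu) at 228 ± 27.0 and 147 ± 26.4 FPKM, and the transcription factor gene Xbp1 at 38.6 ± 9.33 and 21.3 ± 3.05 FPKM.

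The 35 gene lists fixed before the data were examined were compared with the remaining genes by camera with a preset inter-gene correlation of 0.01. With that setting 8 lists passed, 2 of them higher and 6 lower at PND4, but 0 passed with an estimated correlation (smallest adjusted p = 0.433). An exact permutation of the list means per library also passed 0 lists. Adjusted over 35 lists, it can pass only if most lists reach its smallest possible p together, so this 0 does not count against the 8. Lists at that smallest p had an adjusted p of 0.25 in this permutation. Unadjusted p-values under 0.05 were had by 3 of the 35 lists with the estimated correlation and by 4 with the exact permutation (erythroid, meiotic prophase, mitochondrial ribosomal protein and nuclear respiratory genes, each p = 0.0286, the smallest possible). No member of any list passed over all genes, so the members named below are given as values. The median log2 difference of all tested genes was 0.078, and list medians are read against it. The exact permutation of list means does not remove such a shared shift. The mean of the nuclear respiratory list differed by 0.090, close to that median, so its p does not show a change particular to the list. With median-of-ratios scaling the median of all genes was 0.0086.

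The 13 mitochondrially encoded transcripts had a median log2 difference of -0.42 (adjusted p = 0.446 with an estimated correlation), with 12 of 13 lower, 0 past the test over all genes and 5 lower adjusted over the list alone. The cytochrome oxidase gene mt-Co1 stood at 24512 ± 3265 FPKM at PND1 and 17952 ± 1651 at PND4, and mt-Nd1 at 17698 ± 2322 and 15591 ± 2253 FPKM. These transcripts made up 24.5% ± 1.77 of all listed FPKM at PND1 and 20.50% ± 2.90 at PND4 (exact two-sided permutation p = 0.0857, n = 4 per age), with 24.8% in PND4 replicate 1 against 18.5% to 19.6% in the other PND4 libraries. The 76 tested nuclear-encoded respiratory genes had a median of 0.10 and did not pass (adjusted p = 0.20 with the preset and 0.526 with an estimated correlation), but passed with the preset without PND1 replicate 1 (adjusted p = 0.00997). Atp5b stood at 438 ± 47.0 and 446 ± 21.3 FPKM.

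Globin transcripts, the 3 tested members of the erythroid list, had a median log2 difference of -2.03 (adjusted p = 0.433 with an estimated correlation), with 0 past the test over all genes and 3 lower adjusted over the list alone. Hba-a2 stood at 10.5 ± 5.02 FPKM at PND1 and 2.01 ± 1.66 at PND4, and Hba-a1 at 9.35 ± 5.49 and 1.83 ± 1.54 FPKM. The near-identical copies Hba-a1 and Hba-a2 can share reads. Of the meiotic prophase list 3 members were tested, with a median of -0.85 (adjusted p = 0.446 with an estimated correlation) and 2 lower adjusted over the list alone. The synaptonemal complex gene Sycp3 stood at 6.95 ± 1.35 and 3.45 ± 1.06 FPKM, and Syce2 at 5.30 ± 2.66 and 6.03 ± 1.36 FPKM. This call ended with the stricter filter (median -0.30), and without PND1 replicate 2, 3 or 4 or PND4 replicate 2 or 4 (adjusted p = 0.0510 to 0.0680). With any 1 library left out the median stayed between -0.98 and -0.68.

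The stroma and fibroblast list was higher at PND4, with a median log2 difference of 0.44 over 15 genes (adjusted p = 0.446 with an estimated correlation). Adjusted over the list alone 2 members were higher. These were decorin (Dcn), a matrix proteoglycan, at 19.9 ± 4.56 and 36.1 ± 7.12 FPKM and the transcription factor gene Tcf21 at 8.81 ± 5.19 and 21.7 ± 7.80 FPKM. The call ended with the stricter filter (median 0.14), and without PND1 replicate 2, 3 or 4 or PND4 replicate 3 or 4 (adjusted p = 0.0578 to 0.112). The median fell to 0.24 without PND1 replicate 2, 0.26 without PND1 replicate 3, 0.27 without PND4 replicate 3 and 0.22 without PND4 replicate 4, and it was at most 0.37 with any 1 library left out. The most abundant members were Lox, at 90.1 ± 9.62 and 81.0 ± 19.1 FPKM, and Col3a1, at 29.6 ± 4.24 and 31.9 ± 6.09 FPKM. The 89 cytosolic ribosomal protein genes had a median of 0.11 (adjusted p = 0.526 with an estimated correlation), close to that of all genes, and did not pass with median-of-ratios scaling (median 0.033), without PND1 replicate 3 or without PND4 replicate 1 (adjusted p = 0.0587 and 0.118 without these). Rplp1 stood at 1264 ± 166 and 1371 ± 161 FPKM and Rps2 at 1110 ± 59.7 and 1072 ± 65.6 FPKM.

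The other 3 lists with lower values were interferon response genes (14 tested, median -0.32, adjusted p = 0.526 with an estimated correlation), replication-dependent histones (35 tested, median -0.17, adjusted p = 0.512) and basement membrane genes (16 tested, median -0.16, adjusted p = 0.526), the last 2 p-values also with an estimated correlation. The histone list did not pass with median-of-ratios scaling, although its median was then -0.20 (adjusted p = 0.0742 with the preset correlation). Nor did it pass without PND1 replicate 2 or 4 or PND4 replicate 2 or 3 (adjusted p = 0.0649 to 0.136). The interferon call ended without replicate 1 or 4 of PND1 or replicate 2 or 4 of PND4 (adjusted p = 0.0567 to 0.244), and the basement membrane call without replicate 3 or 4 of PND1 or replicate 2 or 4 of PND4 (adjusted p = 0.0680 to 0.161). Both also ended with the stricter filter, with medians of -0.045 and -0.13. These 3 medians moved with single libraries. That of interferon genes was -0.086 without PND1 replicate 4, -0.53 without PND1 replicate 3 and -0.59 without PND4 replicate 3. That of histones was -0.096 without PND1 replicate 4, -0.11 without PND4 replicate 2 and -0.30 without PND4 replicate 1. That of basement membrane genes was -0.076 without PND1 replicate 4, -0.24 without PND1 replicate 1 and -0.31 without PND4 replicate 3. In the histone list, Hist1h2ap stood at 20.7 ± 2.73 and 13.1 ± 3.80 FPKM. In the interferon list Bst2 stood at 32.7 ± 13.7 and 42.1 ± 20.3 FPKM, and in the basement membrane list Sparc stood at 459 ± 55.4 and 416 ± 42.4 FPKM.

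**Figure D2:**
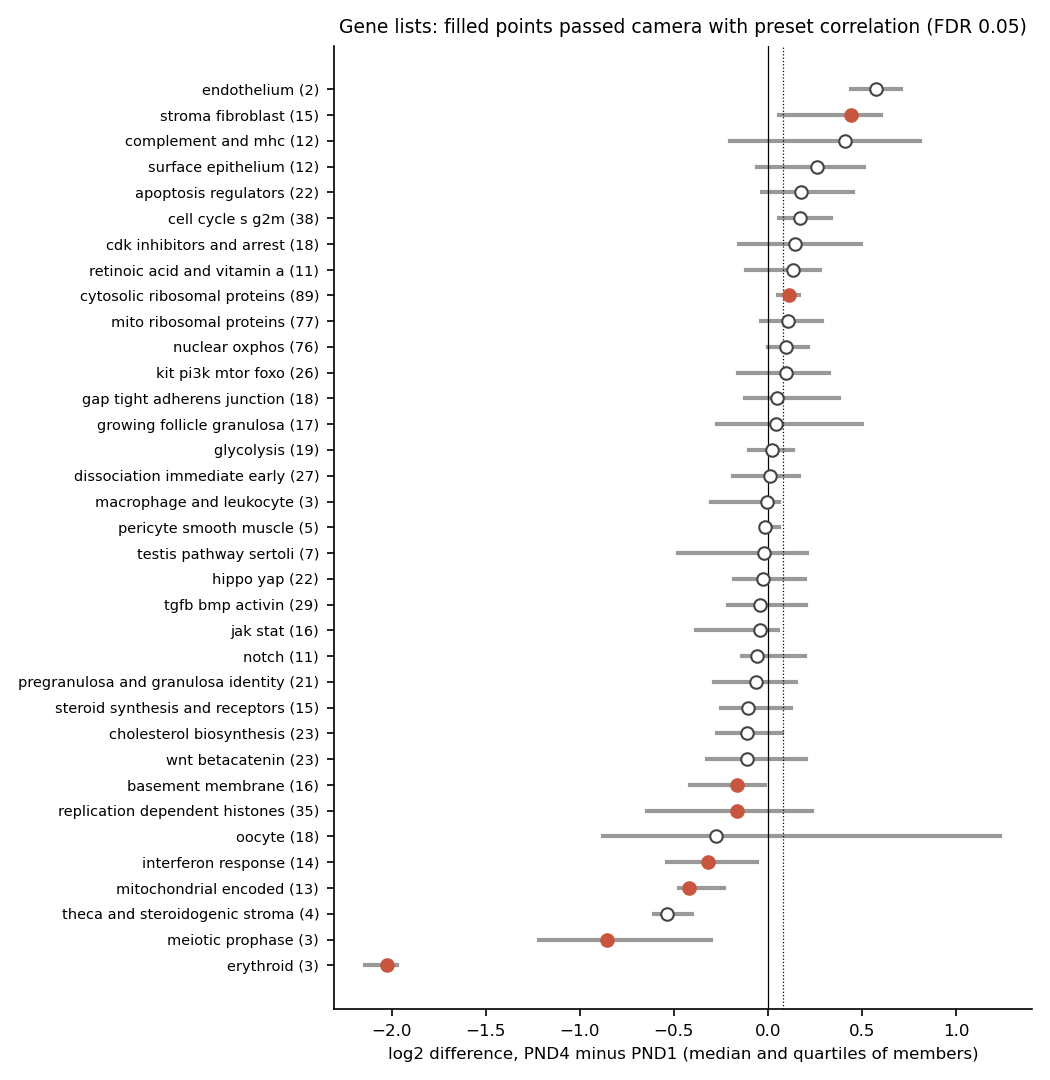
Median log2 difference (horizontal axis, PND4 minus PND1; circles) and quartiles (grey bars) of the tested members of each of 35 gene lists, with the number of tested members in parentheses and the median of all genes (0.078) dotted. Filled circles mark the 8 lists past camera with a preset correlation, of which 0 passed with an estimated correlation.

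The lists closest to the study's question did not pass. The pregranulosa and granulosa identity list (21 tested) had a median log2 difference of -0.064 (adjusted p = 0.20 with the preset correlation), with Krt18 at 500 ± 81.8 and 487 ± 72.9 FPKM. Its median ran from -0.20 without PND1 replicate 2 to 0.0011 without PND4 replicate 1, and its mean, -0.038, turned to 0.040 without PND1 replicate 4 and to 0.0057 without PND1 replicate 3. The growing-follicle list (17 tested) had a median of 0.042 (adjusted p = 0.475 with the preset correlation), and of 0.0069 without PND4 replicate 3 to 0.19 without PND4 replicate 4. Its mean was 0.14, and 0.065 without PND1 replicate 1. Adjusted over the list alone, Serpine2 and the creatine-synthesis enzyme gene Gatm, at 49.4 ± 11.04 and 74.4 ± 10.3 FPKM, were higher in it. The KIT, PI3K, mTOR and FOXO list (26 tested, median 0.10), the TGF-beta, BMP and activin list (29 tested, median -0.040), the NOTCH list (11 tested, median -0.060), the WNT list (23 tested, median -0.11) and the Hippo list (22 tested, median -0.023) did not pass either. The means of the NOTCH and Hippo lists, 0.026 and 0.066, had the opposite sign to their medians. With 1 library left out, the medians of the TGF-beta (-0.092 to 0.074), NOTCH (-0.20 to 0.19) and Hippo (-0.060 to 0.11) lists took both signs, and those of the KIT (0.023 to 0.15) and WNT (-0.17 to -0.0062) lists kept theirs. The WNT list passed with the preset correlation without PND4 replicate 3 (adjusted p = 0.0276). In the Hippo list the kinase-adaptor gene Mob1a stood at 10.9 ± 4.64 and 37.5 ± 20.8 FPKM and was higher adjusted over the list alone. The S and G2/M list (38 tested, median 0.17) and the list of cell-cycle inhibitors (18 tested, median 0.15) did not pass. Without PND1 replicate 1 the S and G2/M median was 0.0052, so that library carried the difference, and without PND4 replicate 3 the list passed with the preset correlation (median 0.20, adjusted p = 0.0478). The median of the inhibitors was 0.059 without PND1 replicate 1, 0.070 without PND1 replicate 2 and 0.26 without PND1 replicate 3, and their mean, 0.059, turned to -0.062 without PND1 replicate 1 and to -0.0062 without PND4 replicate 2. In the inhibitor list, over all 8 libraries, the most abundant members Cdkn1a and Ccng1 stood at 79.5 ± 8.40 and 117 ± 30.6 FPKM, and at 58.4 ± 11.7 and 86.0 ± 13.5 FPKM. Of the 18 inhibitor genes, 12 were higher and 6 lower at PND4. Cdkn2b was among the lower ones, at 23.2 ± 4.93 and 8.92 ± 6.34 FPKM.

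The complement and major histocompatibility list (12 tested, median 0.41, adjusted p = 0.0946 with the preset and 0.481 with an estimated correlation) did not pass. Its median was 0.27 without PND1 replicate 3. Adjusted over the list alone, 5 of its members were higher and 1 lower. Of the 5, B2m, the shared light chain of class I molecules, stood at 144 ± 30.9 and 240 ± 43.7 FPKM, H2-K1 at 32.2 ± 11.04 and 55.2 ± 7.09 FPKM, and H2-D1 at 17.2 ± 2.07 and 30.9 ± 3.25 FPKM. These class I genes are close paralogs and can share reads. The member with lower values was the complement inhibitor gene Serping1, at 14.6 ± 4.21 and 7.92 ± 3.21 FPKM.

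Summed FPKM of markers of other cell types was compared by exact two-sided permutation (4 libraries per age, smallest possible p = 0.0286), and 0 of 10 sums passed Benjamini-Hochberg adjustment, while 2 had an unadjusted p under 0.05. Adjusted over 10 sums, this test can pass only if most of them reach that smallest p together. A change in a single cell type could therefore not have passed. Stroma markers summed to 230 ± 8.77 FPKM at PND1 and 274 ± 28.7 at PND4, and erythroid markers to 29.1 ± 14.2 and 5.24 ± 4.62 FPKM (each exact p = 0.0286, adjusted p = 0.143). The unadjusted p was 0.0571 for stroma without any 1 PND1 library and for erythroid markers without any 1 PND4 library. The differences then stayed at 39.6 to 46.3 FPKM for stroma and -25.9 to -22.2 FPKM for erythroid markers. This p rose with the smaller, unequal groups and not with an overlap of the ages. Oocyte markers summed to 192 ± 69.4 and 267 ± 159 FPKM, meiotic prophase markers to 17.5 ± 2.82 and 11.5 ± 3.75 FPKM, and endothelial markers to 7.55 ± 4.40 and 12.5 ± 1.73 FPKM. Leukocyte markers summed to 19.2 ± 9.77 and 30.9 ± 32.8 FPKM, theca and steroidogenic stroma markers to 43.4 ± 5.91 and 35.1 ± 14.3 FPKM, pericyte and smooth muscle markers to 1076 ± 331 and 991 ± 269 FPKM, and surface epithelium markers to 1186 ± 278 and 1185 ± 218 FPKM. Single libraries set the direction of several of these differences. The PND4 minus PND1 difference of the oocyte sum was -2.09 FPKM without PND4 replicate 3, and that of the leukocyte sum -3.79 FPKM without PND4 replicate 1. That of the pericyte sum was 79.7 FPKM without PND1 replicate 2 and 12.4 FPKM without PND4 replicate 3, and that of surface epithelium went from -137 FPKM without PND1 replicate 2 to 96.2 FPKM without PND4 replicate 1.

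**Figure D3:**
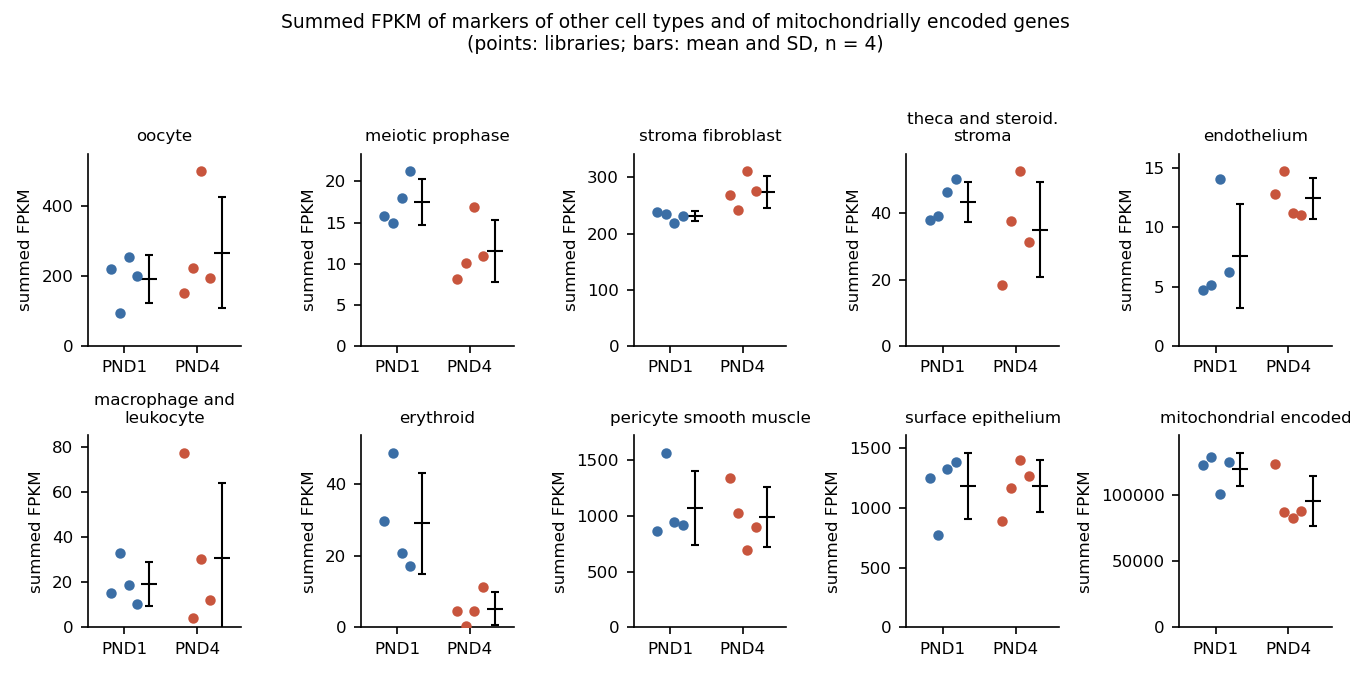
Summed FPKM (vertical axes, linear, from 0) of marker lists in each PND1 and PND4 library (points), with the mean and SD of 4 libraries (bars, ending at the axis where the SD exceeds the mean). The ages do not overlap for stroma and erythroid markers, and PND4 replicate 1 lies among the PND1 libraries for mitochondrially encoded genes.

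The libraries did not separate by age as a whole. The median correlation across genes was 0.906 between PND1 libraries, 0.905 between PND4 libraries and 0.907 between ages. The first principal component held 27.7% of the variance and the second 23.4%, and neither separated the ages (exact permutation p = 0.486 and 0.314 for age). The first set both replicate 1 libraries apart from the rest (-55.5 at PND1 and -40.9 at PND4). The second set these libraries apart from each other, with -48.1 for PND1 replicate 1 and 57.5 for PND4 replicate 1. In the authors' deposited table, 0 genes had a q-value under 0.05, and 772 genes had a p-value under 0.05. The smallest q-value was 0.107. Gm16272 had that value and shared it with other genes, Serpine2 among them, so the authors' test did not set Gm16272 apart. Of these 772 genes in the authors' deposited table, 441 were higher and 331 lower at PND4, and 386 also had an unadjusted p under 0.05 in the limma test.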

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

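A library was singled out where its gap to the nearest of the other libraries of its age took up most of the range of that age. Of 141 groups of 4 libraries examined, covering library measures, marker sums and the genes whose values are given here, 14 met this. For independent groups with a normal spread the rule gives about 1 in 20, or 7.05. The groups here overlap and FPKM values can be skewed, so 14 against 7.05 is no test. PND4 replicate 1 had 24.8% of listed FPKM from mitochondrially encoded genes against 18.5% to 19.6% in the other PND4 libraries, and their summed FPKM was 123110 against 82170 to 88101. The same library had 26.2 FPKM of Foxl2 against 13.3 to 15.4, 15.4 FPKM of Fst against 6.61 to 7.67, and 379 FPKM of Krt18 against 507 to 531. PND4 replicate 3 had 61.3 FPKM of Zp3 against 10.9 to 13.4, 83.3 FPKM of Padi6 against 19.1 to 27.1, and 2.40 FPKM of Lgr5 against 0.720 to 0.894. PND4 replicate 4 had 35.8 FPKM of H2-D1 against 29.0 to 29.5. Endothelial markers summed to 14.1 FPKM in PND1 replicate 3 against 4.72 to 6.27 in the other PND1 libraries. Pericyte and smooth muscle markers summed to 1569 FPKM in PND1 replicate 2 against 862 to 950, and the same library had 378 FPKM of Krt18 against 531 to 552 in the other PND1 libraries. Tcf21 stood at 16.6 FPKM in PND1 replicate 1 against 5.82 to 6.80. Amh stood at 0.239 FPKM in PND1 replicate 4 and at 0 in the other PND1 libraries.

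The 3 tests of mitochondrially encoded genes in this part were chosen after the result was seen. The mean log2 value over the 13 genes was lower at PND4 by -0.35, and an exact permutation test did not pass (p = 0.0857). Without the 2 libraries numbered 1, which list the most genes at 0, the difference was -0.46. With median-of-ratios scaling it was -0.43 (SD 0.22 at PND1 and 0.38 at PND4, exact p = 0.0857). Neither setting can decide the source, because values already seen made a smaller difference unlikely. PND4 replicate 1 was high for these genes, and that scaling lowered the median of all genes from 0.078 to 0.0086. The values show only that the difference was no smaller without those libraries or with that scaling. The median of nuclear-encoded respiratory genes lay 0.019 above that of all genes, and above that of the mitochondrially encoded genes by more than the spread between its members (SD 0.29), which argues against lower expression of the whole respiratory chain. A difference in mitochondrial RNA content with age, in cell damage during dissociation or in cell makeup stays open and was not tested.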

How the results depend on the processing

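Gm16272 was the gene called in every setting, with 1 gene in all of them except array weights, chosen after seeing the data, which gave 2, adding H19 (log2 difference -1.55, adjusted p = 0.0414). Leaving out each library in turn gave 1 gene each time. With the replicate number as a block, 1 gene and 8 lists passed. Same-numbered libraries had deviation correlations of 0.046, -0.0088, 0.032 and 0.12, not all above 0.1. For 1 of the 4 numbers both libraries correlated best with their own number. These values do not show a pairing by number, and they cannot exclude a shared litter, day or batch. Both libraries numbered 1 listed the most genes at 0 (1234 and 1097). With the block 687 genes had an unadjusted p under 0.05 (limma), against 635 without it. The stricter filter (at least 5 FPKM in 4 libraries) kept 4 of the 8 list calls and gave 5 lists in all, while 0 passed with an estimated correlation. With permutation of list means 0 passed too, but that adjusted test could pass only if most lists reached its smallest p together. Leaving out 1 library gave 3 to 12 lists (3 without PND1 replicate 4, 4 without PND1 replicate 3, PND4 replicate 2 or PND4 replicate 4, 5 without PND1 replicate 2, 12 without PND4 replicate 3, which kept 6 of the 8). Those gained without PND4 replicate 3 were the oocyte, theca, cholesterol synthesis, Sertoli, WNT and S and G2/M lists (camera with the preset correlation, adjusted p = 0.0144 to 0.0478). The theca and steroidogenic stroma list (4 tested, median -0.54, adjusted p = 0.0705 with all libraries) also passed without PND1 replicate 1 (adjusted p = 0.0155). Median-of-ratios scaling, upper-quartile scaling and rescaling without mitochondrial and ribosomal-RNA-like entries each gave 6 lists, losing ribosomal proteins and histones. Without both libraries numbered 1 there were 10. The direction of Foxl2 turned with array weights (-0.11) and without both libraries numbered 1 (-0.25). Leaving out 1 library gave differences of -0.077 to 0.23 for Foxl2, negative without replicate 1 of either age, and of -0.12 to 0.055 for Kitl, positive without PND1 replicate 2. As mean log2 values, leukocyte (-0.078), pericyte (0.00342) and surface epithelium (0.22) differences changed sign against the summed FPKM, as did surface epithelium without its most abundant member (11.8 FPKM). In none of these was a call involved, and the cause was not tested. Leaving out 1 library gave differences in summed FPKM of -2.09 (without PND4 replicate 3) to 115 for oocyte, -3.79 (without PND4 replicate 1) to 20.6 for leukocyte, -202 to 79.7 for pericyte and -137 to 96.2 for surface epithelium markers. Of the 10 marker sums, 0 passed as mean log2 values, without the most abundant member or with 1 library left out. These adjusted tests, too, can pass only if most sums reach the smallest p together. With 6 libraries or the paired sign-flip the exact tests cannot pass, so these give values with no test. The planned count tests were not run because they need counts. The unknown depth sets no limit that could be computed for genes listed at 0.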

Other observations

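Tests of the amino acid genes against dissociation stress, both oocyte tests, the count of splits for genes past the adjusted threshold and the comparison with splits that part the replicate 1 libraries were chosen after the results were seen. Of the genes with the smallest p, several belong to the response that ATF4 drives when amino acids are scarce. A list of this response was written after 8 members had been seen, and the other 35 tested members had not been looked at one by one. Of those 35, 34 had higher PND4 values, 11 with an unadjusted p under 0.05, and 0 passed over all genes (limma). Over all 10756 genes tested, 437 were higher and 198 lower with such a p, against 243 and 323 with median-of-ratios scaling. The 34 were counted without that scaling, and the members are not independent (estimated correlation 0.21), so the count overstates their agreement. Aldh18a1, for the entry enzyme of proline synthesis, stood at 18.4 ± 2.60 FPKM at PND1 and 28.2 ± 2.96 at PND4 (SD, n = 4). The aminoacyl-tRNA synthetase genes Gars and Aars stood at 109 ± 7.49 and 144 ± 15.9 FPKM, and at 27.1 ± 7.45 and 42.4 ± 3.31 FPKM. The serine and glycine enzyme gene Shmt2 stood at 72.4 ± 6.19 and 93.6 ± 9.53 FPKM, and Slc7a1, the exception, at 49.3 ± 8.96 and 46.0 ± 7.51 FPKM.

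A hypothesis is that amino acid response genes share higher expression at PND4. Over the 35 members not looked at, the mean log2 value was higher by 0.41, with an exact two-sided permutation p of 0.0571, which missed 0.05. For this group, median-of-ratios scaling and camera were chosen after seeing the data. With that scaling the mean was higher by 0.33 (exact p = 0.0286, the smallest possible), and camera with an estimated correlation gave an unadjusted p of 0.0529. Stress from dissociation may raise ATF4 targets too, and the immediate-early and heat-shock list does not decide this. It differed by -0.018, with 14 members higher, 13 lower and a spread between members (SD 0.33) as wide as the rise looked for. Whether the genes share a rise stays open, as 4 libraries per age missed the threshold.

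Oocyte genes went in opposite directions. Of the 18 tested members of the oocyte list, which was fixed in advance, 9 were higher and 9 lower at PND4, and the list mean did not pass (exact p = 0.943). That mean, 0.13, depended on single libraries. It was 0.495 without PND4 replicate 1 and -0.37 without PND4 replicate 3, where the list passed camera with the preset correlation (median -0.63, adjusted p = 0.0216). Padi6 stood at 8.90 ± 8.86 FPKM at PND1 and 37.6 ± 30.7 at PND4, while Figla was listed at 7.99, 1.87, 2.07 and 3.89 FPKM at PND1 and at 0, 0, 1.25 and 0.263 FPKM at PND4. The log2 differences of the 18 members had an SD of 1.31, the widest of the 70 assignments of libraries to ages (exact p = 0.0286, the smallest possible), where the median assignment gave 0.59. Without PND4 replicate 3, the library richest in oocyte markers, the SD was 1.25 (exact p = 0.0286). A different number of carried-over oocytes would move the members in 1 direction, but by unlike amounts, since low values move less on log2(FPKM + 1). The SD therefore cannot decide on oocyte number, though it stayed wide without that library. Nor can the signs decide, since 9 higher and 9 lower can also arise with no difference. Only 2 members were higher and 2 lower with an unadjusted p under 0.05 (limma), and the list median depended on PND4 replicate 3. A difference in the number or the stage of the carried-over oocytes stays open, and stage was not tested apart from age.

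The counts of calls do not exclude chance. Of the 35 splits of the 8 libraries into 4 and 4, 6 gave at least as many genes past the adjusted threshold as the real 1 (highest other split 3). For lists by camera with preset correlation it was also 6, with 8 real and 12 in the highest other split. For genes with an unadjusted p under 0.05 it was 6 again, with 635 real and 873 in the highest other split. For both counts of genes, the 5 other splits as large put the 2 replicate 1 libraries in the same group. These libraries lie apart from the rest in the first principal component and at opposite ends of the second. Among the 20 splits that part these libraries as the real one does, the real one was highest for genes with an unadjusted p under 0.05 (635, next 578) and for genes past the adjusted threshold (1, next 0), but 3 of them, the real one included, gave at least 8 lists (highest other 10). These 20 splits are too few for a share under 0.05. Gm16272 was the gene listed at 0 throughout 1 age and at 5 FPKM or more throughout the other. In 4 of the other splits at least 1 gene had such a pattern, with 2 in the highest.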
